A study of Homo sapiens with 16 samples.

How the data were processed

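Total RNA from 16 human esophageal biopsies was sequenced, 6 from healthy controls and 10 from people with active eosinophilic esophagitis (EoE), a chronic inflammation of the esophagus with eosinophils in the epithelium. Per the labels, RNA was isolated with either of a pair of column kits, and which biopsy was handled with which kit is not stated. Each biopsy is 1 sample with 1 column of values, and no sample was pooled or left out.

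The submitters' processing notes name TopHat2 2.04, Bowtie2 2.03 and Cufflinks (version not given) and the build hg19, without the role or order of the tools, and the gene annotation is not given. The deposited values were read as FPKM (fragments scaled by the length of the gene and by the mapped fragments of the sample) per gene locus, since they are decimal, have the layout of a Cufflinks gene table and are not whole numbers, while the header names no unit. No later scaling by the authors is recorded. The table held 31666 loci under 28480 gene names, and the 4082 loci that share a name were kept apart. Loci on the Y chromosome, XIST and TSIX were left out of every step (185 loci), which left 31481. A name had been turned into a date in 27 loci, which were kept under that text. All 4507 loci that span under 90 bp were listed at 0 in every sample, and 8984 loci were 0 in all samples.

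Read and fragment totals were not used here, since the table holds none, so the depth per sample is unknown, and no counting interval or detection floor is given. The summed FPKM ran from 468162 to 1466506 per sample. This spread came from a few loci under 150 bp: 7 samples (2 controls, 5 EoE) held a locus above 100000 FPKM, such as MIR3661 at 251115 FPKM or more in 5 samples. Shares of the summed FPKM were therefore taken over loci that span 150 bp or more. A value of 0 can be a failed estimate: of 4899 loci with a median of 10 FPKM or more, 18 were under 0.001 FPKM in 1 or more samples, with 1 to 6 such loci per sample. A named gene with a value of 0 or under 0.001 FPKM is described as such, with the range or highest value of its groups in place of a mean.

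The design, the gene lists, the rule for named genes and the alternatives, except those said to be chosen after seeing the data, were fixed before the data were examined. Genes with 0.5 FPKM or more in at least 6 samples, whatever their group, were tested (13707 loci). EoE was compared with control on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (2-group design, empirical Bayes with a trend on mean expression, two-sided), and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. A size of 2-fold (log2 difference of 1) was counted as well. The offset of 0.5 shrinks the log2 difference of genes near or below 0.5 FPKM, so their differences are smaller than the ratio of the means. Standard errors (SE) are the moderated ones of limma, on the log2 scale. All tests were repeated after rescaling each sample by its median ratio to the geometric mean over tested genes, called the rescaled values. "Rose" and "fell" refer to the test on the deposited scale, and counts on the rescaled values are given beside them.

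The named genes were the 12 largest rises and the 12 largest falls among genes past the test whose 10 EoE values all lay on 1 side of the control median, without immunoglobulin and T cell receptor segments, HLA genes, genes often deleted between people and names that are only a clone or accession. Up to 4 members of each list with the largest log2 difference past the test were added, and a set of genes named in all cases: CCL26, POSTN, CAPN14, ALOX15, IL13, TSLP, FLG, DSG1, CLC and BANCR. This gave 123 genes. Genes outside this rule are said to be chosen after their values were seen.

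The 29 lists covered eosinophil, mast cell, T cell, B and plasma cell, macrophage and dendritic cell, and neutrophil markers, type 2 cytokines and receptors, type 1 and type 17 cytokines and response, IL-13 response genes, chemokines, cornified envelope and epithelial differentiation, junction and desmosome genes, protease inhibitors, kallikreins and other epithelial proteases, basal layer genes, wound and stress keratins, proliferation genes, extracellular matrix and fibrosis genes, smooth muscle genes, endothelial genes, columnar and gland genes, arachidonic acid metabolism, ion, proton and water transport, interferon-stimulated genes, nerve and neurotrophin genes, long noncoding RNAs, immediate-early genes (a sign of handling), replication-dependent histones (a sign of RNA selection) and ribosomal protein genes (a sign of scaling). A gene can stand in more than 1 list, as ALOX15, CAPN14, HPGDS and SERPINB2 do. Lists with 5 or more tested members (27) were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, which tests the list alone. A list level was the mean log2(FPKM + 0.5) of its tested members in a sample, and group levels were compared with a two-sided exact permutation test over all splits of 16 samples into 6 and 10, adjusted over the lists. Relations between list levels within the 10 EoE samples used Pearson's r and Spearman's rho with a two-sided permutation test of 100000 orders, and all 40320 orders once 2 samples were left out. Measures per sample were compared with the same exact permutation test.

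Alternatives were pseudocounts of 0.1 and 1, no filter on low values, a filter of 2 FPKM, rescaling, quantile normalization, array weights, robust empirical Bayes, an exact Mann-Whitney test, the first component of the residuals as a covariate, an estimated inter-gene correlation, list medians in place of means, and leaving out each sample in turn. Chosen after seeing the data were fits on the samples with and without a locus above 100000 FPKM, a fit without loci under 150 bp, scaling to estimated fragments outside the 50 most abundant genes, and rescaled list levels and relations. Fragments were estimated as FPKM times the exon length of the gene's name in GENCODE 29, which gave a length for 89.4% of tested loci. GENCODE served for lengths and gene types only, since its build differs from that of the file. Coordinates are those of the file's loci on hg19, counted from 1.

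The limma steps were tested on simulated data with the same 13707 genes, independent of each other and without a shift common to a sample. On the log2 scale, 67, 67 and 66 genes were changed by 0.5, 1 and 2. Of these, 44.8%, 85.1% and 98.5% were recovered, and 4.4% of the calls were false. These rates hold for few changed genes and do not describe the real comparison, where most genes were called. The permutation test on list levels called 6.5% of simulated unchanged lists and 95.5% of lists shifted by 2 SD. Simulated unrelated pairs passed the relation test in 5.5% of cases. The other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.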

Results

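Gene expression was measured by RNA sequencing in biopsies of esophageal tissue from 6 healthy controls and 10 people with active EoE. Each biopsy gave 1 library. The values are FPKM per gene locus, 13707 loci passed the filter on low values, and the depth per library is unknown. Between 12387 and 13070 loci reached 0.5 FPKM in a control biopsy and between 13149 and 13882 in an EoE biopsy. The comparison asked which genes differ in expression between active EoE and healthy esophagus, which is the design the submitters state.

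In EoE, most tested genes that answer to interleukin 13 (IL-13), and most mast cell, eosinophil and cell cycle genes, rose, and most genes of the differentiated squamous epithelium fell. None of the gene lists passed the camera test with an estimated inter-gene correlation (lowest adjusted p = 0.139, with 4 of 27 lists at an unadjusted p under 0.05). CCL26 (7:75398842-75419064), the chemokine eotaxin-3 that attracts eosinophils, had a mean of 1.53 ± 1.95 FPKM (SD, n = 6) in controls and 630 ± 383 FPKM (SD, n = 10) in EoE, a log2 difference of 8.35 (SE 0.46, adjusted p = 1.06e-09), higher in 10 of 10 EoE biopsies than the control median. ALOX15 (17:4534214-4545589), a 15-lipoxygenase, went from 0.277 ± 0.223 to 370 ± 247 FPKM, and POSTN (13:38136719-38183563), which encodes the matrix protein periostin, from 0.644 ± 0.522 to 279 ± 271 FPKM. CRISP3 (6:49695092-49712168), a cysteine-rich secretory protein, showed the largest fall, from 600 ± 208 FPKM (SD, n = 6) to 7.35 ± 12.4 FPKM (SD, n = 10), with a log2 difference of -7.61 (SE 0.769, adjusted p = 7.6e-07) and 0 of 10 EoE biopsies above the control median.

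The 12 largest rises were CCL26, ALOX15, POSTN, TNFAIP6, CDH26, CPA3, IGJ, CXCL1, ANO1, ATP13A5, NEFM and SLC9A3, with log2 differences from 8.35 down to 4.77. CDH26 (20:58533471-58608829), a cadherin, rose from 3.75 ± 3.53 to 231 ± 50.3 FPKM. ANO1 (11:69924408-70035652), a calcium-activated chloride channel, rose from 2.97 ± 1.41 to 102 ± 38.2 FPKM, and SLC9A3 (5:473334-524549), a sodium-proton exchanger, from 1.24 ± 0.5 to 47.1 ± 13.5 FPKM. NEFM (8:24771274-24776606), a neurofilament subunit, rose from 0.379 ± 0.118 to 45.1 ± 40.9 FPKM. TNFAIP6 was listed at 0 in 1 control, reached 0.491 FPKM in the others, and ranged from 0.732 to 321 FPKM in EoE. The 12 largest falls were CRISP3, SFTA2, FAM25A, HCG22, CES1, MUC21, EPGN, KRTAP3-2, FNDC4, MT1G, SPINK7 and SYNPO2L, with log2 differences from -7.61 to -4.54. MUC21 (6:30951485-30957675), a membrane mucin, fell from 976 ± 273 to 79.5 ± 101 FPKM, and SPINK7 (5:147691990-147695481), an inhibitor of serine proteases, from 834 ± 191 to 50.1 ± 41.6 FPKM. CES1, a carboxylesterase, fell from 47.9 ± 31.4 to 1.52 ± 2.87 FPKM, and EPGN, a ligand of the epidermal growth factor receptor, from 42.5 ± 4.33 to 2.05 ± 3.11 FPKM. SFTA2 and HCG22 were listed at 0 in 1 EoE biopsy, where their highest values were 12.3 and 11.5 FPKM against 46.5 to 83.1 and 33.5 to 79.2 FPKM in controls. SYNPO2L was listed at 0 in 2 EoE biopsies and KRTAP3-2 in 4, with highest values of 1.76 and 0.339 FPKM against 6.05 to 35.1 and 3.19 to 52.5 FPKM in controls.

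**Figure D1:**
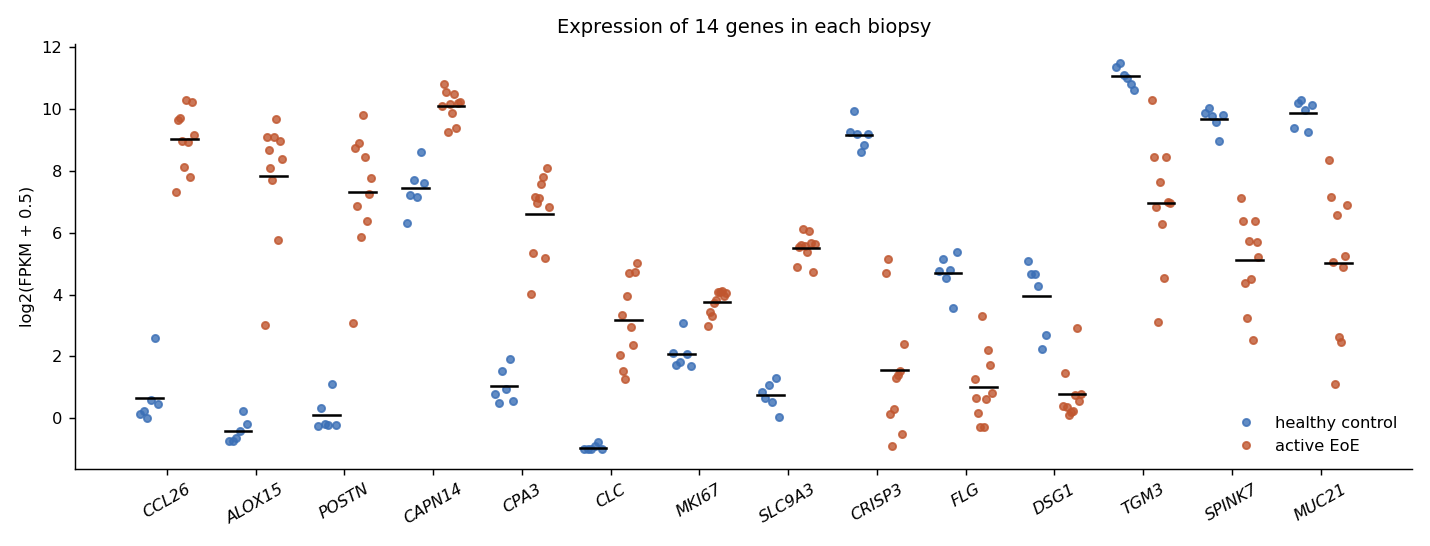
Expression of 14 named genes in each biopsy, as log2(FPKM + 0.5) on the vertical axis, with 1 point per biopsy (6 healthy control, 10 active EoE) and a bar at the group mean. The means of CCL26 lie 8.35 log2 units apart and those of CRISP3 -7.61, EoE minus control.

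Most tested genes were higher in EoE on the deposited scale, where the median log2 difference over all 13707 genes was 0.41. The test called 9321 genes, of which 8007 rose and 1314 fell (85.9% higher), and 1753 of them differed at least 2-fold (1255 higher, 498 lower). After rescaling, the median log2 difference was 0.0087 and 6247 genes passed, 3065 higher and 3182 lower (49.1% higher), with 1493 at 2-fold or more (578 higher, 915 lower). On both scales 4379 genes were called in 1 direction, and 93 were called in opposite directions. Of the 1753 genes at 2-fold or more, 1720 were still past the test after rescaling, and 1076 were called at 2-fold in 1 direction on both scales. On the deposited scale the groups did not overlap in 3656 of the 13707 genes, where chance gives 0.025% of genes. The shift common to most genes can part the groups as well, and the count was not taken after rescaling. Protein-coding genes made up 11852 of the tested loci, and 1104 of these rose and 436 fell at least 2-fold, against 510 and 814 after rescaling. Of 202 tested loci named as long noncoding, 16 rose and 8 fell at least 2-fold on the deposited scale, against 11 and 13 after rescaling. The log2 differences given here are on the deposited scale unless said to be rescaled, and a gene that moved with the median of all genes differs by 0.41 on it.

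The make-up of the libraries differed with the group. The 50 highest genes of each biopsy held 51.3% ± 3.05 of the summed FPKM in controls (SD, n = 6) and 37.2% ± 2.79 in EoE (SD, n = 10; exact permutation p = 0.000125, the smallest that all splits into 6 and 10 can give). Genes of the mitochondrial chromosome held 5.35% ± 0.728 in controls (SD, n = 6) and 11.3% ± 2.96 in EoE (SD, n = 10; exact permutation p = 0.000624).

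**Figure D2:**
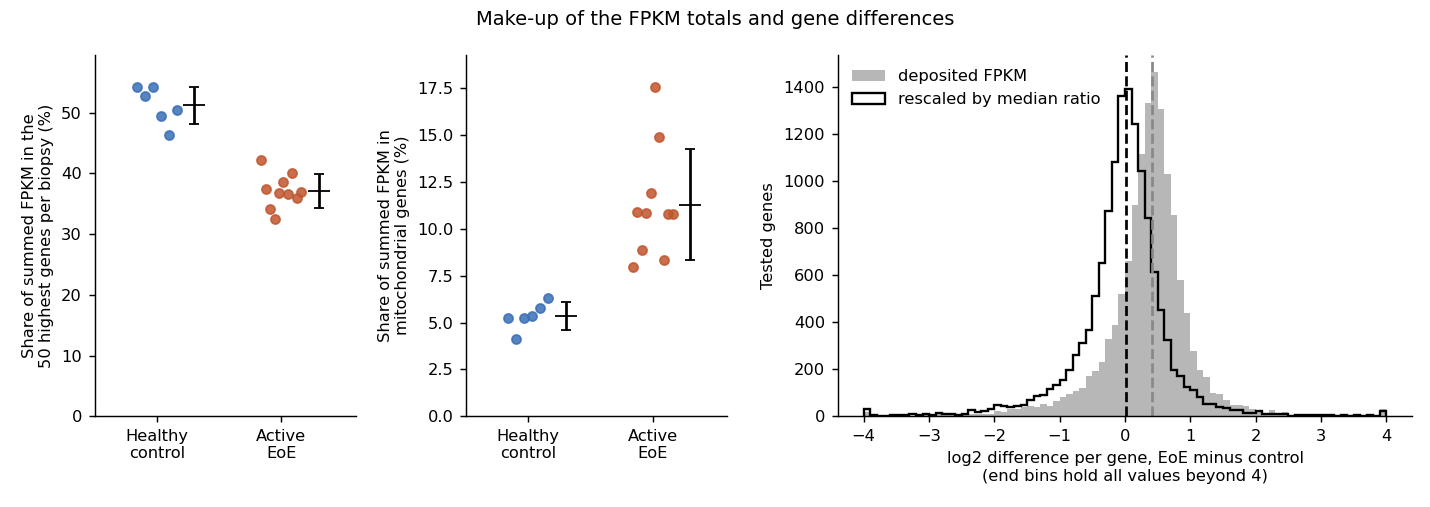
Share of the summed FPKM in the 50 highest genes of each biopsy and in mitochondrial genes (percent, loci of 150 bp or more, 1 point per biopsy, bars at mean ± SD), and the number of tested genes by log2 difference, EoE minus control, on the deposited and the rescaled values. The top 50 genes held 51.3% in controls and 37.2% in EoE, and the dashed medians of the gene differences stand at 0.41 and 0.0087.

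IL-13 response genes rose in 11 of 13 tested members and fell in 2, with the same counts after rescaling. Beside CCL26, ALOX15, POSTN, CDH26 and TNFAIP6, CAPN14 (2:31395922-31456724), a calpain protease, rose from 194 ± 107 to 1159 ± 364 FPKM (log2 difference 2.67). CCL17, a chemokine for T helper 2 cells, fell by 1.07. ARG1, arginase 1, fell as well, and was listed at 0 in 1 EoE biopsy with a highest EoE value of 0.368 FPKM, against 0.502 to 4.3 FPKM in controls. The list passed camera (adjusted p = 0.026), with adjusted p = 0.57 with an estimated correlation. Its level rose by 3.61 log2 units (2.0 ± 0.309 in controls, SD, n = 6, and 5.61 ± 0.584 in EoE, SD, n = 10; exact permutation p = 0.000125, adjusted p = 0.000362), and by 3.26 after rescaling.

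Type 2 cytokines and receptors rose in 7 of 9 tested members and fell in 1, against 5 and 1 after rescaling (camera adjusted p = 0.262, and 0.013 after rescaling, where adjusted p = 0.277 with an estimated correlation). IL13 (5:131993865-131996801) was listed at 0 in 5 of 6 controls, at 0.0346 FPKM in the other, and ranged from 0.284 to 1.73 FPKM in EoE. IL1RL1, the receptor of IL-33, rose by a log2 difference of 2.29, IL17RB, the receptor of IL-25, by 2.06 and CSF2RB, the common beta chain of the receptors for IL-3, IL-5 and GM-CSF, by 2.02. TSLP rose from 1.75 ± 0.713 to 3.39 ± 1.62 FPKM (log2 difference 0.74, adjusted p = 0.0112), but not after rescaling (0.37, adjusted p = 0.202). IL13RA1, a chain of the IL-13 receptor, fell by 0.42. Type 1 and type 17 cytokines and response genes rose in 2 of 8 tested members (1 when adjusted over the list alone), IL12RB2 among them, and fell in 1, IL12A, against 1 and 2 after rescaling (camera adjusted p = 0.0994). The log2 difference of IL12RB2 was 0.39 (adjusted p = 0.0404), which did not pass after rescaling (0.19, adjusted p = 0.318) or in 9 of the 16 fits that left out 1 sample, and that of IL12A was -1.68. The list's median was 0.01 and its mean -0.10.

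Mast cell markers rose in 11 of 12 tested members and fell in 1, with the same counts after rescaling. CPA3 (3:148583043-148614872), a mast cell carboxypeptidase, rose from 1.7 ± 0.946 to 129 ± 83.2 FPKM, the tryptase gene TPSAB1 from 2.13 ± 0.656 to 67.3 ± 48.2 FPKM, and CTSG, cathepsin G, by a log2 difference of 4.39. FCER1A, the alpha chain of the high-affinity IgE receptor, which dendritic cells also carry, fell by 1.13. The list passed camera (adjusted p = 0.0272; adjusted p = 0.671 with an estimated correlation), but not without healthy control replicate 5 (adjusted p = 0.053). Eosinophil markers rose in 5 of 5 tested members on both scales, while 8 of the 13 members in the table were too low to be tested. CLC, the Charcot-Leyden crystal protein, was listed at 0 in 4 of 6 controls, reached 0.0831 FPKM in the rest, and ranged from 1.92 to 32.2 FPKM in EoE. PRG2, the major basic protein, rose by 1.76. CCR3, the eotaxin receptor, was listed at 0 in 4 controls, reached 0.0248 FPKM in the rest, and ranged from 0.262 to 1.65 FPKM in EoE. The camera test of this list gave adjusted p = 0.106, and 0.0025 after rescaling (adjusted p = 0.277 with an estimated correlation).

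T cell markers rose in 10 of 10 tested members, against 6 of 10 after rescaling (camera adjusted p = 0.106, and 0.00662 after rescaling, where adjusted p = 0.494 with an estimated correlation), with CD3D at 1.25, LCK at 1.07, CD2 at 0.96 and CD3E at 0.95. B and plasma cell markers rose in 3 of 4 tested members on both scales, too few for a list test. IGJ, the immunoglobulin joining chain, rose by 5.26 and POU2AF1, a B cell coactivator, by 1.0. MZB1 was listed at 0 in 4 controls, reached 0.617 FPKM in the rest, and ranged from 0.128 to 9.66 FPKM in EoE, and CD79A differed by 0.71 (adjusted p = 0.0809). Macrophage and dendritic cell markers rose in 10 of 14 tested members and fell in 3, against 7 and 3 after rescaling (camera adjusted p = 0.939). The complement genes C1QA, C1QB and C1QC, made by macrophages, rose by 1.74, 1.87 and 1.71, while CD207 and CD1A, found in Langerhans cells, fell by 1.80 and 0.96 and CD68 fell by 0.88. Of 10 neutrophil markers in the table, 3 were tested and the others were too low. FPR1 rose (0.86) and CXCR2 and S100A12 fell (-1.73 and -2.56) on both scales.

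Chemokines rose in 9 of 16 tested members and fell in 1, against 7 and 2 after rescaling (camera adjusted p = 0.961). CXCL1, a neutrophil chemokine, rose from 0.284 ± 0.327 to 39.9 ± 49.3 FPKM and IL8, another one, by 2.35. CXCL6 was listed at 0 in 1 control and CCL18 in 2, with highest control values of 0.31 and 0.962 FPKM, and their EoE values ranged from 2.37 to 26.8 and from 0.143 to 6.98 FPKM. CXCL14, an epithelial chemokine, fell by 1.68. Interferon-stimulated genes rose in 18 of 19 tested members, against 14 after rescaling, and passed camera (adjusted p = 0.0127; adjusted p = 0.671 with an estimated correlation). IFI27 rose from 99.2 ± 71.7 to 590 ± 252 FPKM, IFIT3 by 2.34 and DDX58, a sensor of viral RNA, by 2.23, and ISG20 fell by 0.56. The type 1 chemokines CXCL9 and CXCL10 differed by 0.02 and -0.0011 (adjusted p = 0.949 and 0.998).

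Cornified envelope and epithelial differentiation genes fell in 22 of 28 tested members and rose in 1, against 24 and 1 after rescaling. TGM3 (20:2276613-2321725), a transglutaminase that crosslinks the envelope, fell from 2172 ± 492 to 264 ± 371 FPKM, CRCT1 from 1497 ± 376 to 138 ± 105 FPKM, and FLG (1:152274651-152297679), filaggrin, from 27.4 ± 10.2 to 2.29 ± 2.78 FPKM. RPTN, repetin, was the member that rose, from 0.851 ± 0.464 to 25.5 ± 18.9 FPKM. The list passed camera (adjusted p = 1.26e-21; adjusted p = 0.139 with an estimated correlation), and its level fell by 1.86 log2 units (exact permutation p = 0.000125, adjusted p = 0.000362) and by 2.30 after rescaling.

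Junction and desmosome genes rose in 8 of 24 tested members and fell in 6, against 3 and 12 after rescaling. DSG1 (18:28898052-28937393), a desmosomal cadherin, fell from 18.8 ± 11.6 to 1.63 ± 1.99 FPKM, and the claudin CLDN10 fell by 3.06, while PKP2, a desmosomal plakophilin, rose by 2.52. CLDN17 was listed at 0 in 1 EoE biopsy, with a highest EoE value of 6.28 FPKM, against 0.514 to 8.56 FPKM in controls. The list passed camera as lower than other genes (adjusted p = 0.0228; adjusted p = 0.15 with an estimated correlation), while its median was 0.11, its mean -0.13 and fry gave the direction up (adjusted p = 0.015), which turned down after rescaling (adjusted p = 0.000213). Protease inhibitors rose in 8 of 22 tested members and fell in 9, against 6 and 9 after rescaling. SPINK7 fell as above, SPINK8 was listed at 0 in 6 of 10 EoE biopsies and reached 0.53 FPKM in the rest, against 2.4 to 14.5 FPKM in controls, and SERPINB4 and TIMP1 rose by 3.60 and 3.01. Camera called the list lower (adjusted p = 0.00107, and 0.21 with an estimated correlation), but not after rescaling (adjusted p = 0.177). By the exact permutation test the level of protease inhibitors passed as lower after rescaling (-0.598, adjusted p = 0.0034) but not before (-0.178, adjusted p = 0.1945). Fry also called them lower only after rescaling (adjusted p = 0.00183, against 0.197). With the median over members, their level on the deposited scale rose (0.46). Kallikreins and other epithelial proteases rose in 6 of 19 tested members and fell in 6, against 3 and 6 after rescaling. CTSC, cathepsin C, rose from 17 ± 7.56 to 313 ± 102 FPKM, and KLK7 by 1.76, but KLK7 passed neither after rescaling (1.31, adjusted p = 0.112) nor without healthy control replicate 5 or 6 (highest adjusted p = 0.0539). TMPRSS11B, a membrane serine protease, fell from 749 ± 155 to 256 ± 159 FPKM. Camera also called this list lower (adjusted p = 0.0233; adjusted p = 0.654 with an estimated correlation), but not after rescaling (adjusted p = 0.429), with a median of -0.32 and a mean of 0.13.

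Basal layer genes rose in 8 of 15 tested members and fell in 0, against 1 and 2 after rescaling (camera adjusted p = 0.51). LAMB3, a laminin chain of the basement membrane, differed by 0.97, SOX2 by 0.92 and CAV1 by 0.82, and none of these 3 passed after rescaling. COL17A1 and COL7A1 were lower after rescaling (-0.92 and -0.87), and LAMA3 was higher (0.41). Wound and stress keratins rose in 1 of 9 tested members, KRT8, and fell in 3, against 0 and 4 after rescaling. KRT6B fell from 412 ± 179 to 90.3 ± 131 FPKM, KRT6C by 3.10 and KRT7 by 1.95. These keratins passed camera as lower (adjusted p = 0.0272, and 0.381 with an estimated correlation), but not after rescaling (adjusted p = 0.223). Their median was 0.08 and their mean -0.60. The other tests went the opposite way with the scale. By the exact permutation test their level passed as lower after rescaling (-1.05, adjusted p = 0.00533) but not before (adjusted p = 0.0637). Fry also called them lower only after rescaling (adjusted p = 0.0099, against 0.506). Proliferation genes rose in 25 of 25 tested members, against 20 after rescaling, and passed camera (adjusted p = 4.97e-05; adjusted p = 0.654 with an estimated correlation). MKI67 (10:129894925-129924468), the Ki-67 antigen, rose from 4.02 ± 2.02 to 13.4 ± 3.34 FPKM, TOP2A by 1.64, AURKA by 1.6 and BUB1 by 1.55.

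Extracellular matrix and fibrosis genes rose in 14 of 22 tested members and fell in 1, against 12 and 1 after rescaling (camera adjusted p = 0.482, and 0.00643 after rescaling, where adjusted p = 0.501 with an estimated correlation). LOX, which crosslinks collagen, rose by 2.67, COL8A2 by 2.29 and LUM by 1.75, and TGFB1 fell by 0.82. MMP12 was listed at 0 in 1 control, with a highest control value of 0.329 FPKM, and ranged from 0.851 to 7.4 FPKM in EoE. Smooth muscle genes rose in 2 of 6 tested members, ACTA2 and SMTN, and in 0 when adjusted over the list alone or after rescaling, where SMTN changed sign (0.34 and -0.036; camera adjusted p = 0.939), and the calls were lost in 6 and 11 of the 16 fits that left out 1 sample. Endothelial genes rose in 7 of 13 tested members and fell in 1, against 5 and 1 after rescaling (camera adjusted p = 0.919). ICAM1, CLDN5 and VCAM1 rose by 1.64, 1.61 and 1.22, and ESAM fell from 24.6 ± 4.8 to 5.46 ± 2.13 FPKM. Of 8 tested columnar and gland genes, LYZ, lysozyme, rose on both scales (1.5) and the others did not pass (camera adjusted p = 0.36).

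Genes of arachidonic acid metabolism rose in 7 of 17 tested members and fell in 2 on both scales (camera adjusted p = 0.939). Beside ALOX15, PTGES, a prostaglandin E synthase, rose by 2.78 and HPGDS, the prostaglandin D synthase of mast cells, by 2.58, while ALOX12, a 12-lipoxygenase, fell from 56.5 ± 24.3 to 5.07 ± 3.29 FPKM and PLA2G4A fell by 0.62. Genes of ion, proton and water transport rose in 9 of 17 tested members and fell in 5, against 7 and 6 after rescaling (camera adjusted p = 0.939). Beside ANO1 and SLC9A3, the potassium channel KCNJ2 rose by 3.87 and the anion exchanger SLC26A4 by 3.49. SLC4A4, CA12, SCNN1B, SCNN1G and CLIC3 fell, by 0.65 to 1.25. Nerve and neurotrophin genes rose in 6 of 7 tested members, against 5 after rescaling (camera adjusted p = 0.106, and 0.0025 after rescaling, where adjusted p = 0.277 with an estimated correlation). NTRK2, the receptor of brain-derived neurotrophic factor, rose from 2.57 ± 0.76 to 48.4 ± 16.7 FPKM and GFRA3 by 1.0.

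Long noncoding RNAs rose in 7 of 15 tested members and fell in 2, against 3 and 3 after rescaling (camera adjusted p = 0.338). BANCR (9:71911597-71921972) was listed at 0 in 5 of 6 controls, at 0.0381 FPKM in the other, and ranged from 0.114 to 25.1 FPKM in EoE. SNHG1 rose by 1.18, and LINC00152 and UCA1 fell by 1.12 and 0.97. Immediate-early genes, which respond to tissue handling, rose in 3 of 13 tested members (EGR1, ATF3 and NR4A1 at 1.82, 1.73 and 1.3) and fell in 2 (ZFP36 and IER3 at -1.04 and -1.01), against 2 and 4 after rescaling (camera adjusted p = 0.106). Replication-dependent histones fell in 9 of 11 tested members and rose in 0, against 10 and 0 after rescaling, and passed camera (adjusted p = 6.4e-09; adjusted p = 0.21 with an estimated correlation). HIST1H2BC fell from 15.2 ± 3.37 to 2.87 ± 1.65 FPKM, and HIST1H1C and HIST1H4H by 1.52 and 1.51, while the proliferation genes rose. HIST1H3D was under 0.001 FPKM in 2 EoE biopsies, with a highest EoE value of 2.24 FPKM, against 2.45 to 6.47 FPKM in controls. These transcripts mostly lack a poly(A) tail, so their level also varies with how RNA is selected. Ribosomal protein genes rose in 21 of 28 tested members, such as RPS16 (0.55), RPL32 (0.53) and RPL27A (0.48), but in 0 after rescaling, where 2 fell, RPLP0 among them (camera adjusted p = 0.262).

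The counts adjusted over the list alone equalled those over all genes in 27 of the 29 lists, the exceptions being type 1 and type 17 genes and smooth muscle genes. At the preset correlation 10 of 27 lists passed camera, 7 of them also after rescaling, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 21 lists moved on balance in 1 direction and 25 changed in either direction. These counts are on the deposited scale, where the shift common to most genes also moves a list up. After rescaling, the basal layer, smooth muscle, endothelial, long noncoding and ribosomal protein lists no longer passed fry (adjusted p = 0.402 to 0.866). Junction genes turned down, and protease inhibitors and wound keratins passed as lower. Camera gave the direction down beside a positive median for chemokines, type 1 and type 17 genes, basal layer, smooth muscle, endothelial, columnar, arachidonic acid, transport, long noncoding and immediate-early lists, none past its threshold on the deposited scale, and for junction genes and wound keratins, which passed. The exact permutation test on list levels was passed by 22 of 29 lists, 18 higher and 4 lower, and after rescaling by 20, 14 higher and 6 lower. Eosinophil, mast cell, and B and plasma cell levels rose by 2.02, 2.97 and 2.32, and those of proliferation and interferon-stimulated genes by 1.20 and 1.52. Histone, neutrophil, and junction levels fell by 1.07, 1.14 and 0.13, though the junction level rose with the median over members in place of the mean (0.36). The neutrophil level rests on 3 of 10 listed genes, of which FPR1 rose, so it does not show that neutrophils were fewer. Ribosomal protein and long noncoding levels rose on the deposited scale (0.36 and 0.25) and had the opposite sign after rescaling (-0.10 and -0.11), without passing. CCL17, ARG1, IL13RA1, FCER1A, CD79A, CD1A, CD68, CXCL14, ISG20, CXCL9, CXCL10, COL17A1, COL7A1, LAMA3, TGFB1, PLA2G4A, SLC4A4, CA12, SCNN1B, SCNN1G, CLIC3, IER3 and RPLP0 stand outside the rule for named genes and were chosen after their values were seen. Reads of near-identical genes, such as TPSAB1 and TPSB2 or KRT6B and KRT6C, may be shared between them.

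**Figure D3:**
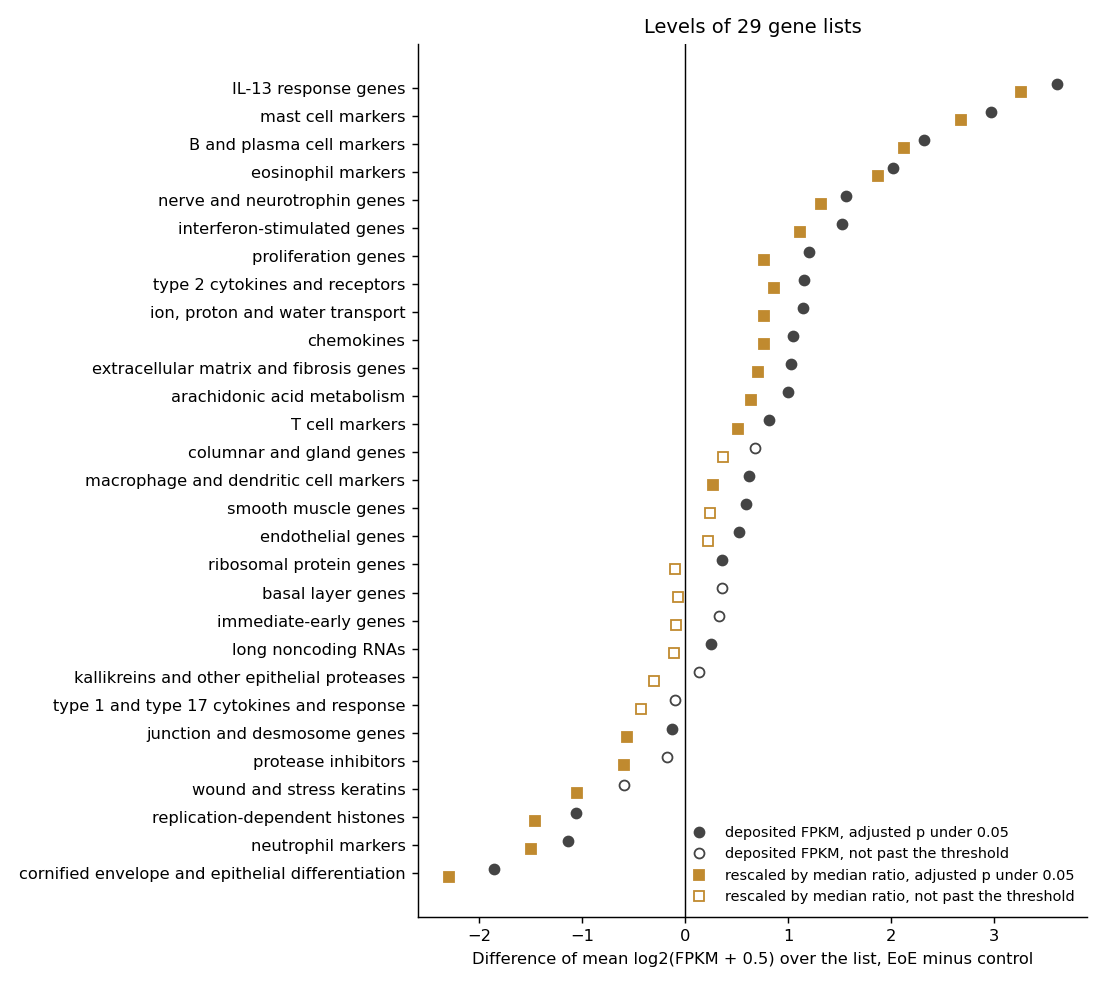
Difference of the mean log2(FPKM + 0.5) over each of 29 gene lists, EoE minus control, on the deposited (circles) and rescaled (squares) values, with filled symbols where the exact permutation test passed after adjustment over the lists. IL-13 response genes stand highest at 3.61 and cornified envelope genes lowest at -1.86 on the deposited scale, and ribosomal protein, basal layer, immediate-early, long noncoding, and kallikrein and protease lists change sign after rescaling.

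Within the 10 EoE biopsies, the eosinophil level was set against the levels of 8 other lists. None of the 8 relations passed adjustment by Pearson's r or by Spearman's rho, and 1 had an unadjusted p under 0.05 by either. That relation, with the mast cell level, had r = 0.71 (permutation p = 0.0255, adjusted p = 0.204) and rho = 0.73 (permutation p = 0.0206, adjusted p = 0.165). Without the 2 biopsies farthest from the median eosinophil level, r was 0.60 and rho 0.57 (exact permutation p = 0.114 and 0.151, n = 8). The eosinophil level had r = 0.41 with the IL-13 response level (rho = 0.39; permutation p = 0.244 and 0.261) and r = 0.0053 with the T cell level (rho = 0.13; permutation p = 0.989 and 0.733). It had r = -0.30 with the cornified envelope level (rho = -0.25; permutation p = 0.384 and 0.492). With proliferation, matrix, smooth muscle and endothelial levels, r was -0.12, 0.10, 0.40 and 0.17, and rho was 0.018, 0.18, 0.49 and 0.35. The permutation p for these r were 0.756, 0.783, 0.267 and 0.635, and those for rho were 0.973, 0.631, 0.156 and 0.33. The EoE biopsies with and without a locus above 100000 FPKM number 5 each, too few for a relation within either.

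Samples parted by group on the first principal component (56.8% of the variance), where controls lay between -67.8 and -41.1 and EoE between -1.40 and 62.1. The second component held 8.33%. Across genes, which are not independent replicates, r between samples was 0.966 to 0.983 within controls, 0.923 to 0.977 within EoE and 0.856 to 0.958 between groups. The labels give no batch. Among the 9 samples without a locus above 100000 FPKM (4 controls, 5 EoE) the test called 8509 genes, and among the 7 with such a locus (2 controls, 5 EoE) it called 2500.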

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

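No test in this part was chosen after the result was seen. The gap between the highest or lowest sample and its neighbour, divided by the range of the group on the log2 scale, exceeded the 95% limit of Dixon's test in 23 of 246 groups for named genes (9 control, 14 EoE), where chance gives about 12.3. It did so in 5 of 58 groups for list levels, where chance gives about 2.9, and in 0 of 14 groups for measures per sample. Chance alone passes about 1 in 20 groups. No explanation was tested for these values.

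Healthy control replicate 5 held 7 of the 8 high values of named genes in controls, the 1 low value and both high list levels, and MKI67 was high in replicate 4. Replicate 5 also lay nearest the EoE biopsies on the first principal component (-41.1). Without it, 9404 genes passed the test, 1929 of them at 2-fold or more. In controls, the highest value lay apart for CCL26 (ratio 0.775; 5.5 FPKM against 1.01 in the next), CDH26 (0.672; 10.9 against 3.23), MKI67 (0.71; 8.03 against 3.79) and POU2AF1 (0.697; 0.719 against 0.182). The same held for CCL18 (0.847; 0.962 against 0.0894 FPKM) and MZB1 (0.877; 0.617 against 0.052). For IL13 and BANCR the ratio was 1, since the other 5 controls were listed at 0 and the highest values were 0.0346 and 0.0381 FPKM. The lowest control lay apart for TPSB2 (ratio 0.642; 0.631 against 1.1 FPKM). The highest control list levels lay apart for macrophage and dendritic cell markers (0.797; 2.35 against 1.95) and ribosomal protein genes (0.672; 9.61 against 9.28).

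In EoE, the highest biopsy lay apart for CES1 (ratio 0.552; 9.55 FPKM against 1.5), MT1G (0.511; 35.3 against 7.03), SYNPO2L (0.574; 1.76 against 0.45), DSG1 (0.513; 7.11 against 2.29) and KRT6C (0.468; 242 against 38.6). ACTA2 (0.563; 15.3 against 3.89 FPKM) and EGR1 (0.552; 153 against 20.1) also had a high biopsy. The lowest biopsy lay apart for IGJ (0.59; 1.04 against 24.4 FPKM), CD2 (0.505; 2.15 against 3.73), TMPRSS11B (0.48; 11 against 68.7), KLK7 (0.543; 7.05 against 52.2) and TOP2A (0.51; 15.9 against 22.6). KCNJ2 (0.526; 8.17 against 19.3 FPKM) had a low biopsy as well. Among list levels, the highest EoE biopsy lay apart for basal layer genes (0.562; 5.38 against 4.63) and immediate-early genes (0.657; 5.77 against 4.05), and the lowest for T cell markers (0.496; 0.528 against 1.07).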

How the results depend on the processing

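Fits on the samples with and without a locus above 100000 FPKM, without loci under 150 bp, scaled to fragments outside the 50 most abundant genes, and rescaled list levels and relations were chosen after seeing the data. Of 123 named genes, 73 kept their call and direction in all 30 alternatives, and 4 more in the 29 that gave a value for them, since 14 genes were below the filter of 2 FPKM. Of the 123, 18 lost or turned it under any of the 3 scalings, 43 in either sample subset and 4 under the 9 other alternatives. Leaving out each sample in turn gave 8656 to 9436 genes past the test (7451 to 8180 higher, 1200 to 1366 lower), 1660 to 1941 of them at 2-fold (1170 to 1425 higher, 462 to 542 lower), and 9 to 11 lists. In those 16 fits 4 named genes lost the call: SMTN in 11 fits (log2 difference 0.28 to 0.40), IL12RB2 in 9 (0.34 to 0.45), ACTA2 in 6 (0.59 to 0.96) and KLK7 without healthy control replicates 5 and 6 (lowest 1.44). Camera gained T cell markers without healthy control replicate 1 (adjusted p = 0.0367) or active EoE replicate 8 (0.037), type 1 and type 17 genes without healthy control replicate 4 (0.0489) and immediate-early genes without active EoE replicate 4 (0.032), and lost mast cell markers without healthy control replicate 5 (0.053).

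A pseudocount of 0.1 gave 1962 genes at 2-fold higher, since low genes gain size. Rescaling gave 3065 higher and 3182 lower, and at 2-fold 578 and 915. Quantile normalization gave 6157 (3397 higher, 2760 lower), and at 2-fold 554 higher and 791 lower. Scaling to fragments outside the 50 most abundant genes gave 5171 higher and 2082 lower, and 793 higher at 2-fold. These 3 remove part or all of the shift of 0.41 by construction. The samples without a locus above 100000 FPKM gave 1967 higher at 2-fold, and the cause was not tested. Those with one, with only 2 controls, gave 2500 (2020 higher, 480 lower), and 1084 at 2-fold (764 higher, 320 lower). An estimated correlation left 0 lists past camera. The sign turned for SMTN after rescaling (-0.036) and quantile normalization (-0.10), for CLDN17 in the samples with such a locus (0.13), for the levels of long noncoding RNAs (-0.11) and ribosomal protein genes (-0.10) after rescaling, and for the levels of junction genes (0.36), protease inhibitors (0.46) and long noncoding RNAs (-0.17) with the median over members, where the cause was not tested. Rescaling, which lowers EoE values against controls, also turned the levels of basal layer (-0.073), immediate-early (-0.086) and kallikrein and protease genes (-0.31), which passed the test on neither scale. List levels past the test numbered 20 to 23, and relations 0, in each alternative. Not run were alternatives on counts, since the table holds FPKM, and on transcripts, since its loci are genes. The unknown depth leaves the floor of values near 0 unknown.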

Other observations

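The gene groups in the next 2 paragraphs and the tests of the cornified envelope genes were chosen after the values were seen, while the other tests were not. Metallothioneins, which bind zinc and copper, fell in 7 of 8 tested genes on both scales, with a median log2 difference of -1.77 (-2.23 rescaled). MT1G fell from 234 ± 247 to 6.72 ± 10.2 FPKM (SD, n = 6 and 10; adjusted p = 5.38e-05), MT2A from 260 ± 209 to 43.7 ± 12.5 FPKM and MT1X from 375 ± 136 to 161 ± 55.3 FPKM. Of 9 tested genes of the IL-1 family, 5 fell and 0 rose on both scales. IL36A fell from 837 ± 551 to 169 ± 114 FPKM, IL18 from 318 ± 104 to 64.3 ± 19.3 FPKM and the receptor antagonist IL1RN from 1773 ± 377 to 598 ± 162 FPKM, each lower than the control median in 10 of 10 EoE biopsies. IL1A and IL36RN fell by 1.48 and 1.51. S100A8 and S100A9, the calprotectin subunits, fell by 2.16 and 1.84 log2 units and S100A12 by 2.56, while S100A7 differed by 0.67 (adjusted p = 0.702).

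Complement genes rose in 14 of 18 tested members and fell in 0, against 10 and 1 (CD59) after rescaling. CFI rose from 2.08 ± 0.932 to 27.9 ± 8.72 FPKM (SD, n = 6 and 10; adjusted p = 9.13e-09) and CFB from 3.39 ± 0.994 to 36.5 ± 20.4 FPKM, each higher than the control median in 10 of 10 EoE biopsies. On chromosome 6, the interval from 30899127 to 31027655 (hg19, 128529 bp), bounded by SFTA2 and HCG22, held 5 loci of the table, and all 5 fell on both scales: SFTA2 (-5.58), DPCR1 (-2.88), the mucin genes MUC21 (-4.84) and MUC22 (-4.17), and HCG22 (-5.21), with a median of -4.84 (-5.29 rescaled). SFTA2, MUC22 and HCG22 were each listed at 0 in 1 EoE biopsy, and MUC22 reached 7.59 FPKM in EoE against 0.747 to 61.9 FPKM in controls.

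Most tested genes were higher in EoE on the deposited scale, with a median log2 difference of 0.41. Short loci with very high FPKM are argued against as the whole cause, since the median was 0.471 among the samples with no locus above 100000 FPKM. Of the 50 genes most abundant in controls, 27 fell and 12 rose. The 43 of them with an exon length held 33.7% ± 2.77 of estimated fragments in controls (SD, n = 6). In EoE these 43 held 17.4% ± 2.78 (SD, n = 10, exact permutation p = 0.000125). Because the 50 genes were picked by their control values, a lower share in EoE was favoured beforehand. The permutation did not repeat that choice, so neither this p nor the counts of falls and rises test a fall. The scaling below rests on the same 50 genes. Scaling to the fragments outside the 50 left a median of 0.187 (SE 0.0346 for the mean scaling difference), between the bounds set for and against. Loci without a length entered neither the shares nor the scaling factor, so changes in abundant loci among them are not counted. A fall of a few very abundant transcripts may therefore account for part of the shift, and it cannot be told apart from a rise of most genes per cell, nor from disease itself, without counts or a spike-in.

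Cornified envelope genes were lower in EoE. Dilution of the epithelium by cells from outside it, infiltrating or other, would lower basal layer genes as much. This assumes that only the epithelium makes them, which was not tested. The median rescaled log2 difference of basal layer genes lay 2.21 above that of cornified envelope genes. The rescaled basal layer level minus the cornified envelope level per sample also differed between the groups (exact permutation p = 0.000125, the smallest possible). On that assumption, these values argue against dilution as the whole cause. Of 15 basal layer genes, 2 fell and 1 rose after rescaling. A scale set by the abundant epithelial genes themselves is argued against, since a scale moves all genes of a sample alike. The cornified envelope level minus the median of all tested genes in each sample differed by -2.29 between EoE and control (exact permutation p = 0.000125). This value restates the rescaled level difference of -2.30 and adds no separate evidence of the fall. Biopsies that hold more deep and less superficial epithelium cannot be told apart from changed epithelial cells, with more immature and fewer differentiated ones. The median rescaled log2 difference of basal layer genes was -0.02. Their rescaled level differed by -0.073 (exact permutation p = 0.646), and no histology or biopsy depth is given.

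The neurofilament genes NEFL (8:24808469-24814383) and NEFM rose in EoE, NEFL from 0.229 ± 0.122 to 38.4 ± 34.9 FPKM (SD, n = 6 and 10). Nerve tissue in the EoE biopsies is argued against, since 10 other nerve and glial genes had a median of 0.032 FPKM in EoE and a median rescaled log2 difference of -0.012. The most abundant of them, S100B, had 3.69 ± 1.62 FPKM in controls and 3.07 ± 1.78 in EoE. A single biopsy is argued against, since the highest adjusted p of NEFL and NEFM over the 16 fits without 1 sample was 0.000639. Expression of both genes in another cell type of the EoE tissue may be the source, as a hypothesis that these data do not test.

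Chance assignment of samples to the groups is argued against for both gene counts, as far as 100 splits can show. Of 100 splits of the 16 samples into 6 and 10, the real split included, only the real one, 1 of 100, gave as many genes past the test (9321, and at most 84 in the others). The same held for genes at 2-fold or more, where 1 split, the real one, gave 1753 and the highest of the others 4. The splits do not part gene changes from the shift common to most genes. Of the 9321 genes, 4379 kept the call and direction after rescaling.

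Loci under 150 bp had values far above those of other genes in some samples. MIR3661 (5:133561448-133561543) was above 0 in 2 controls and 3 EoE biopsies, at 251115 FPKM or more. MIR5047 was above 0 in 3 controls and 5 EoE biopsies, and D28408 in all 16 samples, at 5937 to 23799 FPKM. MIR570, MIR573, MIR574 and SNORD127 were each above 0 in 1 EoE biopsy.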
